A study of Mus musculus with 4 samples.

How the data were processed

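ChIP-seq of ESR1 was available as processed peak lists for 1 liver and 1 uterus library of female C57BL/6 mice. Per the labels' protocols, 100 mg of pulverised frozen tissue was crosslinked in 1% formaldehyde for 15 minutes and quenched with 125 mM glycine. The 2 input control samples entered through the authors' peak calling and were not analysed here on their own. Whether a library came from 1 animal or from several is not given in the sources used here.

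The authors called peaks separately in each ESR1 library with MACS 1.3.7.1 on the mm9 build, per the submitters' processing notes. Per the file headers, tags of 50 bp were used with 1 control tag set per library, an effective genome size of 2.70 Gb, a band width of 300 bp, a model fold of 15 and a p cutoff of 1e-10, and the local background was taken from the peak region and from 1000, 5000 and 10000 bp around it. The estimated fragment shift parameter d was 115 bp in liver and 106 bp in uterus, per the file headers. The aligner and its filters are not given in the sources used here. The headers give 21226844 total and 20016495 unique tags for the liver ESR1 library, and 23718643 and 22298008 for uterus, so tags that were not unique made up 5.70% and 5.99% of the totals.

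Each peak in the deposited lists carries a count of tags, which is a raw whole-number count that was not scaled to depth. The deposited fold enrichment is a ratio of the ChIP signal to the local background that MACS estimated from the control. The deposited MACS score is 10 times the −log10 of the p-value; 11 liver and 279 uterus peaks have a score of exactly 3100, which looks like a stand-in for p-values too small to store. The deposited false discovery rate is a percent with 2 decimals, so 0 can be an exact 0 or a value below rounding. Peak widths equalled end minus start plus 1 in all 6932 liver and 24836 uterus rows, so both ends are included. Coordinates were taken as 1-based, which this check does not settle. A peak's values depend on the depth of its own library and control, so they were used to rank peaks within a list and not as levels to compare between tissues.

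A peak was called shared if it overlapped a peak of the other list by at least 1 bp. Shares are given with 95% Wilson intervals, and differences of shares with Newcombe intervals. Chance overlap was taken from 1000 random placements of the liver peaks on their own chromosomes, between the first and last peak of either list, and from shifts of 20 and 100 kb. Clustering was set against 200 placements and summit distances against 100. Peaks were divided into deciles, 10 groups of equal size, by fold enrichment, tags, score or width. Medians of shared and single-tissue peaks were compared within a list by a two-sided permutation test of the rank sum (100000 permutations), with bootstrap intervals from 1000 resamples and Benjamini-Hochberg adjustment over 8 tests. Chromosome span was the distance from the first to the last peak of either list. With 1 library per tissue, no test between tissues was possible.

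The overlap count and the permutation test were tested on simulated data. With 1500 of 6932 liver-sized peaks moved onto uterus peaks, 1500 were found. With no difference, the permutation test called 2% of 100 simulated liver lists and 8% of 100 uterus lists. With a factor of 1.1 on fold enrichment the test called 100% of each. Class labels were drawn at random, and fewer permutations were used than in the analysis. The low rates with no difference were therefore set by design, and the clustering of real peaks was not simulated.

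The rule for the peaks to be named, the tests of the main comparisons and most alternatives were fixed before the data were examined; some tests of explanations were chosen later, as stated beside them. The rule named the 8 shared peaks with the smallest sum of ranks of fold enrichment and the 8 liver-only and 8 uterus-only peaks of highest fold enrichment. The alternatives were other overlap rules, stricter thresholds, lists of equal length, other measures of strength, other distances and shifted positions. Motif content, including the estrogen response element, distances to transcription start sites and counts of fixed gene lists near peaks had been planned. They were not analysed here, since they need an mm9 genome and annotation, and coordinates were not converted between builds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.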

Results

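The study mapped where the estrogen receptor alpha, ESR1, sits on chromatin in 2 mouse tissues. ESR1 is a nuclear receptor that binds DNA as a transcription factor and is activated by estrogens; the uterus is a classical estrogen target organ, and the liver also expresses the receptor. Frozen liver and uterus from female C57BL/6 mice aged 8 weeks were crosslinked, and DNA bound to ESR1 was recovered by chromatin immunoprecipitation and sequenced (ChIP-seq). The series held 4 samples, namely an ESR1 library and an input control from each tissue. A peak list was analysed for each of the 2 ESR1 libraries, so each tissue was represented by 1 library and no difference between tissues could be set against a spread between animals. Intervals are 95% intervals; those of shares cover counting error only, and bootstrap intervals cover the variation across peaks of 1 library.

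The libraries were of similar depth. The liver ESR1 library held 20016495 unique tags and its control 18781348, and the uterus ESR1 library held 22298008 and its control 22020520. The peak lists differed far more than the depths. The uterus list held 24836 peaks covering 16.0 Mb, and the liver list held 6932 peaks covering 4.74 Mb. Tags inside peaks made up 8.80% of the unique tags in uterus and 2.42% in liver. Both lists had been called at the same p cutoff of 1e-10, and the highest false discovery rate was 0.66% in liver and 0% in uterus, as rounded in the lists.

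The first comparison asked which ESR1 sites were bound in both tissues and which in only one of the lists. Most sites were found in a single tissue. Of the liver peaks, 1646 overlapped a uterus peak by at least 1 bp, which was 23.7% of the list (Wilson interval 22.8 to 24.8). Of the uterus peaks, 1635 overlapped a liver peak, or 6.58% (6.28 to 6.90). The remaining 5286 liver peaks and 23201 uterus peaks are called liver-only and uterus-only here; the words refer to the called lists, since a site under the cutoff in the other tissue is also counted there. When the liver peaks were placed at random on their own chromosomes, a mean of 94.5 overlapped a uterus peak, with a highest value of 126 in 1000 placements, so the observed overlap was 17.4 times the chance value. Shifting every liver peak by 20 or 100 kb, which keeps the regional clustering of sites, left 157 to 208 overlaps, and against these the observed count was 7.91 to 10.5 times higher. All deposited peaks were used, so regions with many tags and low enrichment, such as those on chromosome 17 described below, count as shared. The overlap was not separated from regions of high background in both libraries. List length also bears on the shares. With 1 partner each, the 6932 liver peaks could overlap only 6932 of the 24836 uterus peaks, which limits the uterus share. A shorter uterus list can only lower the share of liver peaks. Against 6932 uterus peaks drawn at random, which must lower it about in proportion to the list, it was 6.61% (mean of 200 draws, 6.03 to 7.26). Against the 6932 of highest fold enrichment it was 6.09% (5.55 to 6.68). With stricter lists the share of uterus peaks fell to 3.93% at a fold enrichment of at least 10 in both lists and to 4.10% at a MACS score of at least 200. These cuts also shortened the liver list from 6932 peaks to 4343 and 2827. Fewer partners were thus left, and the fall by itself does not show less sharing among stronger sites.

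The overlapping peaks coincided closely in position. There were 1651 overlapping pairs, and the median distance between the liver and the uterus summit was 38 bp (quartiles 14 and 132 bp), against 333 bp for randomly placed peaks (mean of the medians of 100 placements). Summits lay within 50 bp of each other in 57.4% of pairs (55.0 to 59.7), compared with 2.47 to 15.7% in 100 random placements.

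**Figure D1:**
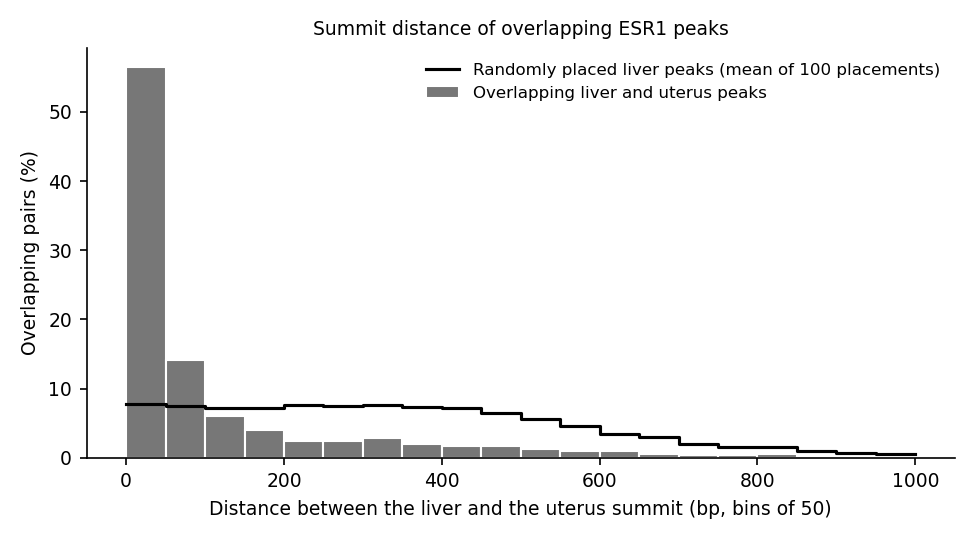
Distance in bp between the liver and the uterus summit for the 1651 overlapping pairs of ESR1 peaks, as a percentage of pairs in bins of 50 bp (bars), and the mean of 100 random placements of the liver peaks (line). The first bin holds 56.5% of the observed pairs and 7.82% of the random ones.

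The strongest shared sites were taken as the 8 pairs with the best summed rank of fold enrichment. Positions are those of the mm9 build as the authors' lists give them, and the fold enrichments are the authors' values per peak, used here to rank peaks within a list. The leading site lay on chromosome 13, at 52152490 to 52153426 in liver (88.4-fold over control, 242 tags) and at 52152511 to 52153521 in uterus (133-fold, 509 tags), with summits 4 bp apart. The next lay on chromosome 7 at 6195767 to 6196825 in liver (82.6-fold, 299 tags), with 112-fold and 329 tags in uterus. A site on chromosome 4 at 41083251 to 41084281 in liver was 66.2-fold enriched there and 109-fold in uterus. One on chromosome 3 at 84087309 to 84088288 was 80.9-fold enriched in liver and 105-fold in uterus, and its summits were 1 bp apart. The others lay on chromosome 5 (113387098 to 113387727 in liver), chromosome 11 (70096988 to 70097614), chromosome 6 (100009563 to 100010521) and chromosome 16 (13494003 to 13494599). Across the 8 sites the summits of the tissues were 1 to 21 bp apart. The chromosome 16 site had 42 tags in liver, at 29.3-fold, and 401 tags in uterus, at 140-fold; these values are not compared between the tissues. Genes near these sites are not named, because an mm9 annotation was not used here.

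Sites with strong signal in a single tissue were present in both lists. The liver-only peak of highest fold enrichment lay on chromosome 18 at 13354822 to 13355481, with 102-fold enrichment and 141 tags. It was followed by peaks on chromosome 15 at 102016574 to 102017320 (76.2-fold, 246 tags) and chromosome 8 at 112496673 to 112497612 (69.8-fold, 330 tags). The 8 leading liver-only peaks ranged from 46.9- to 102-fold, and the nearest uterus summit was between 3.14 and 280 kb away. The leading uterus-only peak lay on chromosome 2 at 81295495 to 81296404, with 176-fold enrichment and 329 tags, and the nearest liver summit was 2087 kb away. The following ones were on chromosome 16 at 73362677 to 73363203 (161-fold, 227 tags), chromosome 12 at 94361961 to 94362620 (157-fold, 274 tags) and chromosome X at 9368386 to 9369037 (149-fold, 215 tags). The 8 leading uterus-only peaks ranged from 141- to 176-fold and had 215 to 448 tags. Their nearest liver summits were 27.1 to 2404 kb away.

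The second comparison asked whether shared and single-tissue sites differed in strength within each list. In liver, shared peaks were stronger by each measure. Their median fold enrichment was 12.0 against 11.0 in liver-only peaks (difference 0.97, bootstrap interval 0.65 to 1.42), and they held a median of 68 tags against 55 (difference 13, 10 to 14.5). In uterus the measures went apart. Shared uterus peaks held more tags, with a median of 72 against 54 (difference 18, 15 to 20), but their median fold enrichment over control was lower, at 12.4 against 14.8 (difference -2.42, -2.86 to -1.90). Shared peaks were also wider, with median widths of 678 against 621 bp in liver and 689 against 573 bp in uterus. A tag count is summed over the whole peak, so a wider peak can hold more. Per kb of peak, the median tags were 94.7 against 87.1 in liver and 97.3 against 90.9 in uterus. A two-sided permutation test of the rank sum across the peaks of a list gave p = 1e-05 for fold enrichment, tags and width in both lists and for the MACS score in liver, the smallest value that 100000 permutations can give. For the MACS score in uterus the same permutation test gave p = 5.1e-04, with shared peaks again higher (medians 231 and 215). The Benjamini-Hochberg adjusted values over the 8 tests were 1.1e-05 and 5.1e-04. Peaks are not replicates, so these values describe the 2 libraries and not the tissues at large. At a MACS score of at least 200 the liver difference in median fold enrichment was 3.03, and with shared peaks defined by summits within 200 bp it was 1.60; the uterus difference was -2.02 and -1.76 under the same alternatives.

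The share of shared peaks changed with strength. Among liver peaks it rose from 16.4% (13.9 to 19.4) in the decile with the fewest tags to 44.2% (40.6 to 48.0) in the decile with the most. Among uterus peaks it rose from 1.81% (1.36 to 2.42) to 10.6% (9.44 to 11.9). By peak width the share rose as well, from 18.2% in the decile of the narrowest peaks to 39.2% in that of the widest in liver and from 2.09% to 13.2% in uterus. By MACS score it rose from 16.3% to 42.7% in liver but only from 5.80% to 9.06% in uterus. Ranked by fold enrichment, the liver list showed 23.2% shared in its lowest decile, 17.0% in the third and 41.4% in the highest. The uterus list showed 14.3% (13.01 to 15.8) in the lowest decile, 4.11% (3.396 to 4.96) in the fifth and 7.73% (6.74 to 8.85) in the highest. At a MACS score of at least 200 in both lists, the highest decile by fold enrichment lay 30.4 percentage points above the lowest in liver, against 18.2 in the full list, while in uterus the difference was -2.39 points, against -6.60. Thus 55.8% of the liver peaks with the most tags and 89.4% of the uterus peaks with the most tags had no called partner in the other tissue.

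**Figure D2:**
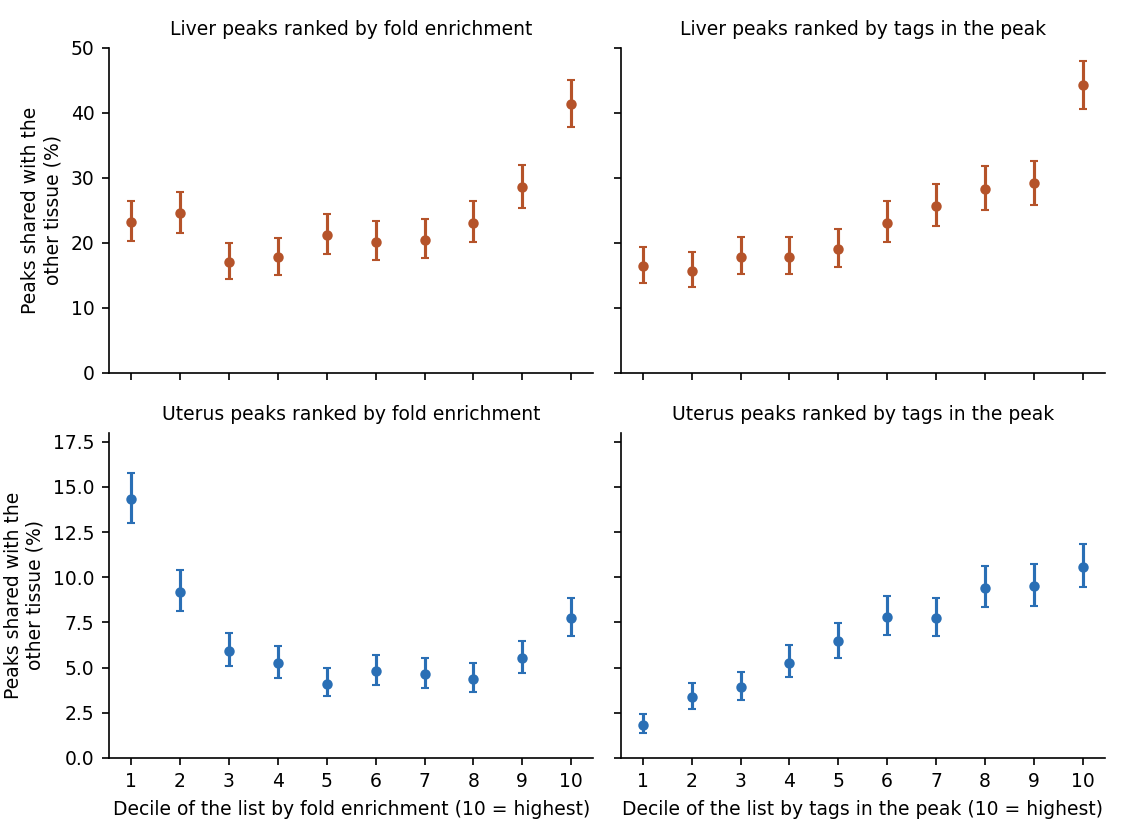
Percentage of peaks shared with the other tissue (y axis, with separate scales for liver and uterus) in each decile of the list ranked by fold enrichment or by tags in the peak (x axis); points are shares and bars 95% Wilson intervals. By tags the share rises to 44.2% in liver and 10.6% in uterus, while by fold enrichment the lowest uterus decile has the highest share, 14.3%.

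Peaks lay in clusters in both tissues. In liver, 40.3% of peaks (39.2 to 41.5) had another liver summit within 10 kb, against 5.81% when the peaks were placed at random on their chromosomes. In uterus the value was 47.5% (46.9 to 48.1) against 18.5%. Single-tissue sites also lay near sites of the other tissue more often than random placement gave. A uterus summit lay within 10 kb of 27.8% of liver-only peaks (26.7 to 29.1), against 15.1% for random positions and at most 16.5% in 200 placements. A liver summit lay within 10 kb of 7.97% of uterus-only peaks (7.63 to 8.33), against 4.51%. Random positions could overlap a peak of the other list and the single-tissue peaks could not, which lowers the observed values relative to chance. Random placement also does not keep the regional density of sites. Liver peaks shifted by 100 kb still overlapped a uterus peak 157 or 170 times, against a mean of 94.5 in random placement. Nearness within 10 kb was not set against shifted peaks, so it was not separated from regional density shared by the lists. At a MACS score of at least 200 the values of the single-tissue peaks were 18.1% and 4.03%, in shorter lists.

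ESR1 peaks were unevenly spread over the chromosomes. Chromosome 11 had the highest density in both tissues, with 4.62 peaks per Mb in liver and 13.7 per Mb in uterus. Chromosome 3 had the lowest density of the autosomes, with 2.07 per Mb in liver and 8.61 per Mb in uterus. Chromosome X stood apart from every autosome. It carried 36 liver peaks, or 0.226 per Mb, and 309 uterus peaks, or 1.94 per Mb, so the mean density of the autosomes was 12.8 times that of X in liver and 5.29 times that of X in uterus. X took up 6.25% of the chromosome span but held 0.519% of the liver peaks (0.375 to 0.718) and 1.24% of the uterus peaks (1.11 to 1.39). The difference between the lists was 0.725 percentage points (0.487 to 0.930), from 1 library each. The X peaks held fewer tags than autosomal ones, with medians of 45 against 58 in liver and 41 against 55 in uterus. Their median fold enrichments were higher, at 14.3 against 11.2 in liver and 17.1 against 14.7 in uterus. Of the peaks on X, 8 were shared in each list.

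**Figure D3:**
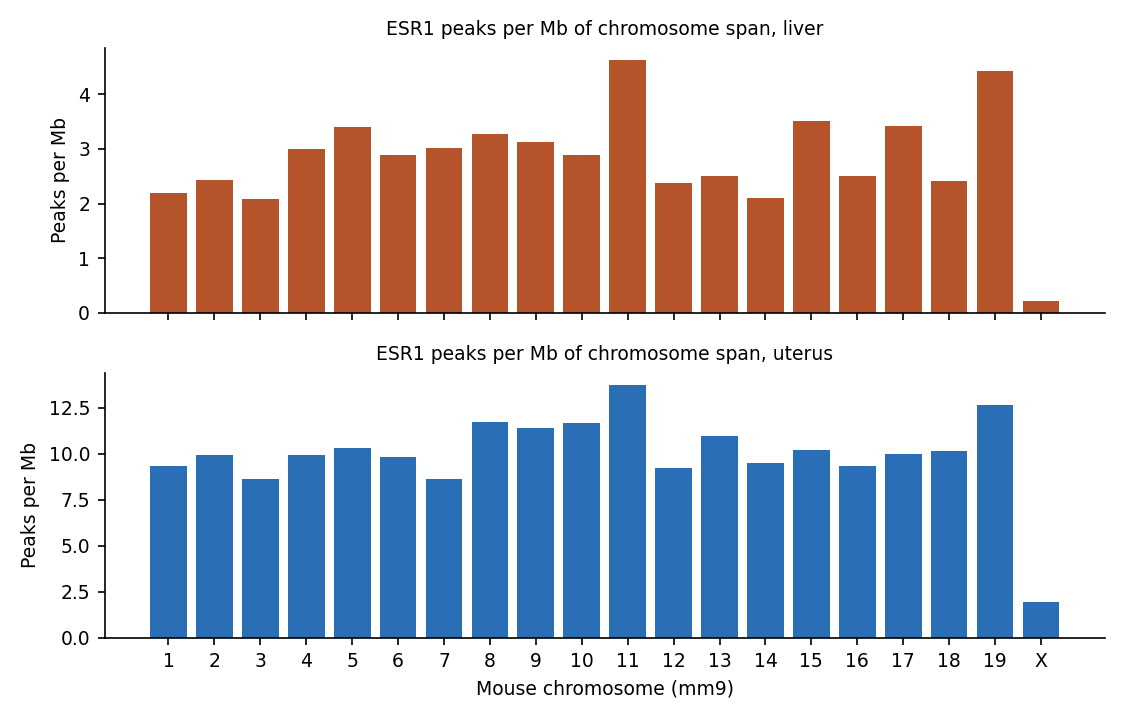
ESR1 peaks per Mb of chromosome span (y axis, separate scales) on each mouse chromosome (x axis, mm9 build) in the liver list (top) and the uterus list (bottom). Chromosome X has 0.226 peaks per Mb in liver and 1.94 in uterus, below all 19 autosomes.

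The 2 peaks with the most tags in each list combined high counts with low enrichment over control. In both lists the highest count lay on chromosome 17, at 39979876 to 39983873 in liver (4003 tags) and 39979844 to 39983870 in uterus (4719 tags), with a fold enrichment over control of only 3.35 and 2.89. The neighbouring peak, at 39984392 to 39985842 in liver, held 1074 tags in liver at 4.75-fold and 1250 in uterus at 4.60-fold. By tags these were followed in liver by a shared peak on chromosome 14 at 26327601 to 26329930 (677 tags, 66.5-fold), where the enrichment was high, and in uterus by a shared peak on chromosome 1 at 38297743 to 38299884 (1033 tags, 75.6-fold). These 4 regions were picked after their values were seen.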

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

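Some tests were chosen after the values they bear on had been seen. These were the tests of local control level and of a weaker liver library, and the removal of the lowest shared and highest uterus-only peaks. The ratio of all X peaks to autosomal peaks with a score of at least 200 was also chosen then. So was the comparison of tags per kb over fold enrichment on X. The other tests here were written down first, but the 5-fold threshold used below was itself chosen after seeing the data.

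The median fold enrichment of shared minus single-tissue peaks was 0.97 in the liver list and -2.42 in the uterus list, opposite directions under the same contrast, although shared peaks held more tags in both; this difference between the tissues was not tested, as each has 1 library. Peak width as the cause was argued against, since within deciles of width the fold difference stayed at -4.16 (bootstrap SE 0.340). Regions under 5-fold, such as that on chromosome 17, are too few to make the difference: 20 of 1635 shared and 41 of 23201 uterus-only peaks lay there. Leaving them out (-2.28, SE 0.256) was thus bound to change little. Leaving out as many of the lowest shared and highest uterus-only peaks still gave -2.25. This cut does not bear on shared peaks of low fold enrichment above 5-fold. The lowest decile of the uterus list (2.89- to 8.38-fold) held 356 of the 1635 shared peaks, and their part in the difference stays open. A higher local control level at shared sites stays open: tags per kb divided by fold enrichment had a median of 7.70 at shared and 6.10 at uterus-only peaks, and 7.94 and 8.03 at shared and liver-only peaks, but this quotient is built from the tags and folds it would explain. Shared uterus peaks had the higher fold enrichment within its deciles, by 2.66 (SE 0.443), which decides nothing, because fold follows tag density there and the density was higher at shared peaks (medians 97.3 and 90.9 tags per kb).

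The small share of uterus peaks found in liver was weighed against technical explanations. If the liver library had been a weaker readout of the same sites, its strongest peaks would lie in the uterus list, but only 44.2% of the liver peaks with the most tags did. A strict overlap rule would miss near sites, but allowing 1000 bp between peaks raised the uterus share only to 7.74%. A lower yield of the liver immunoprecipitation as a part of the difference stays open, as does the tissue itself, which 1 library each leaves inseparable from the library.

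The low density on X was weighed as the third pattern. A deficit limited to sites near the cutoff was argued against, since X held only 0.966% of the highest uterus decile by score (0.650 to 1.43) and 0.432% of the liver one. A halved signal on X stays open: all X peaks per Mb divided by the autosomal peaks per Mb with a score of at least 200 gave 0.192 (0.134 to 0.266) in liver and 0.350 (0.312 to 0.392) in uterus, but how far the score falls when the signal is halved was not measured, so these ratios do not decide. Tags per kb divided by fold enrichment were 0.743 and 0.771 times the autosomal median on X in liver and uterus, outside the range of the autosomes in both lists, but whether X was covered by fewer usable tags was not tested and stays open. No biological explanation was tested, since gene density and sequence of X were not analysed here.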

How the results depend on the processing

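The random trim of the uterus list and the thresholds of 200 on the MACS score and of 5-fold enrichment were chosen after seeing the data, the thresholds because the planned score of 100 and false discovery rate of 1% removed no peak and so test nothing. The alternatives planned for motifs, start sites and gene lists were not run. The shared share of liver peaks (23.7%) became 19.2% with summits within 200 bp, 27.6% with 1000 bp allowed between peaks, 18.1% at 10-fold or more, 6.09% against the uterus list trimmed to equal length by fold enrichment and 19.4% at a score of 200. The shared share of uterus peaks (6.58%) became 5.37%, 7.74%, 3.93%, 6.03% and 4.10% under the same settings. With the uterus list trimmed at random the shares were 6.61% of liver and 6.55% of uterus peaks. Such a trim fixes both values in advance, apart from the chance of the draw. Asking for an overlap of 50% of the shorter peak, or leaving out peaks under 5-fold, kept both shares within their intervals. The ratio to chance (17.4) fell to 10.5, 9.20, 7.91 and 9.68 with liver peaks shifted by -100, -20, 20 and 100 kb, since shifted peaks keep their regional density. The shared share in the highest minus the lowest decile by fold enrichment was 18.2 percentage points in liver, and became 27.8 by tags, 26.4 by score and 30.4 at a score of 200. In uterus it was -6.60, reversed to 8.78 by tags and 3.26 by score, and was -2.39 at a score of 200. The median difference between shared and uterus-only peaks, -2.42 in fold enrichment, likewise reversed to 18 tags and 15.5 in score; it was -1.76 with summits within 200 bp, -2.02 at a score of 200 and -2.28 without peaks under 5-fold. The liver direction held under all of these. A fold enrichment divides by the local control and a tag count does not. The uterus share on X (1.24%) was 1.09% at a score of 200. Peaks with a neighbour in their own list within 10 kb (40.3% in liver, 47.5% in uterus) became 29.0% and 33.2% at 5 kb, 68.6% and 80.7% at 50 kb, and 29.6% and 38.2% at a score of 200. Liver-only and uterus-only peaks near the other list (27.8% and 7.97%) became 16.0% and 4.28% at 5 kb, 70.0% and 26.3% at 50 kb, and 18.1% and 4.03% at a score of 200, where fewer peaks remain. Depth limits the lists to sites past the authors' cutoff, so absence from a list is no evidence of no binding.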

Other observations

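The tests in this part were written down before their values were seen, except the choice of windows.

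Some 1 Mb windows held many sites of both tissues, and a few rich in uterus sites held 0 to 4 liver sites. The 1 Mb window with the most liver peaks lay on chromosome 14 from 26 to 27 Mb (mm9), with 29 liver and 53 uterus peaks, of which 19 and 43 were found in a single tissue. A window on chromosome 2 from 167 to 168 Mb held 26 liver and 43 uterus peaks, and one on chromosome 17 from 46 to 47 Mb held 26 and 37. By contrast, the window on chromosome 12 from 80 to 81 Mb held 60 uterus and 4 liver peaks, chromosome 1 from 92 to 93 Mb held 59 and 3, and chromosome 4 from 105 to 106 Mb, one of the 6 windows richest in uterus-only peaks, held 46 and 0. The other 4 of the 6 windows richest in uterus peaks held 12 to 29 liver peaks, among them the chromosome 14 window. No window among the 6 richest in liver peaks had fewer than 19 uterus peaks. These windows were picked for their counts, and the counts are not set against a spread between animals.

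Overlapping peaks may mark the same bound element in both tissues: 57.4% of the 1651 pairs had summits within 50 bp, above the highest of 100 random placements (15.7%). The closeness depended on strength. In the lowest of 4 equal groups of pairs by uterus fold enrichment, 43.6% (38.9 to 48.4) had summits within 50 bp, against 75.5% (71.2 to 79.4) in the highest group, a difference of -32.0 percentage points (-38.1 to -25.5). Ranked by liver fold enrichment the shares were 40.0% and 76.5%. A summit is also placed less exactly in a weak peak, and that was not separated here.

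Strength in liver and in uterus was positively related across the sites called in both lists. The pairs hold only sites past the authors' cutoff in both lists, so the full range of strength was not covered. No repeat library shows what correlation the same tissue would give. The size of the values below therefore does not tell how far the tissues differ in strength. Across the 1651 pairs, which are sites and not independent replicates, Spearman's rho was 0.24 for tags and 0.38 for fold enrichment (permutation p = 1e-05 each, the smallest that 100000 permutations can give, and 1e-05 after adjustment over the 2 relations). Pearson's r of log2 values was 0.30 and 0.44 (permutation p = 1e-05 each), and 0.27 and 0.44 without the 2 pairs farthest from the liver median.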
